A study of Mus musculus with 8 samples.

How the data were processed

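The series holds 8 samples of mouse mammary tumour RNA, 4 labelled FGFR1 KO and 4 labelled WT, each on 1 2-colour Agilent array. Per the file headers, the arrays were read with Agilent Feature Extraction 11.0.1.1 under its 2-colour gene expression protocol, and the probes were designed against the mouse build mm9. Per the file headers, the median signal and median background columns are spot intensities on a linear scale with no background correction, and the processed signal columns are intensities after background subtraction, spatial detrending and dye normalization within each array. Per the file headers, the ratio column is the log10 of red over green processed signal. The deposited series matrix was found from its values to hold log2 red over green for each array. Its columns correlated at 0.893 to 0.947 with the scanner's ratio and at 0.985 to 0.991 with the values computed here. Their medians were 0.0152, -0.0155, -0.00112 and 0.00458 for FGFR1 KO 1 to 4 and -0.00481, -0.00181, -0.00562 and 0.00171 for WT 1 to 4. How those columns were normalized and centred is not given in the sources used here, while their scale and direction were settled by these correlations.

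The labels disagree on the dyes. The label field names only cy3, while the labelling protocol gives the tumour RNA the red Alexa dye and a universal human reference RNA the green one. By a rule fixed before the data were examined, the channel that varied less within groups was taken as the common reference. Over 23622 spots, the median SD within groups was 0.165 for FGFR1 KO and 0.186 for WT in green against 0.308 and 0.391 in red, and correlations within groups ran from 0.954 to 0.989 in green and from 0.849 to 0.967 in red. Green was therefore taken as the reference and red as the tumour. The 2 channels of an array correlated at 0.850 to 0.915 across spots.

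Values were computed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 on the median signals, in place of the mean signals named beforehand, which were not used here. Arrays were normalized by loess within each array, with control spots and spots that Feature Extraction marked as outliers at weight 0, and the log2 of red over green was taken. Control spots and outlier spots were then left out, and replicate spots of a probe were averaged. Of 55681 distinct probes, 39883 were well above background in red on at least 4 of the 8 arrays, and 39795 of these also had at least 3 values per group and were tested. The depth behind a value was judged by the share of red spots well above background, given per group with the results. Probes were named through their RefSeq accession in an NCBI gene table of assembly GRCm38.p6, which was used for names only. It named 28331 probes for 21368 genes, and unnamed probes kept the identifiers and mm9 coordinates of the files. Each gene was represented by its probe with the highest mean normalized red signal.

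FGFR1 KO was compared with WT by limma's lmFit and eBayes over all 8 arrays, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Gene lists were tested by limma's camera with a preset correlation of 0.01 over 16478 genes with a value on every array, adjusted over the 45 lists. The lists were fixed before the data were examined. Their tested members are 988 distinct genes, and they cover the FGF pathway, other receptor kinases and their ligands, proliferation, mammary epithelial lineages, stromal, immune and other cell types of a tumour piece, and general pathways. Camera with an estimated correlation and the rotation test fry, for a shift in 1 direction and for change in either direction (mixed), were alternatives, and each list's medians per array were compared by an exact permutation test. Members of a list were also adjusted over the list alone. A gene whose probes were not well above background on any array of 1 group has only a bound there. For it, the bright group's mean red signal was set against the higher of the dim probe's own signal and the lowest signal above background per array, after loess and A-quantile normalization, and this bound is open to dye bias without dye swaps.

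The genes named were chosen by a rule fixed before the data were examined: Fgfr1; the most changed genes past the threshold or, where fewer than 5 passed in a direction, the 8 with the smallest p in that direction, without clone and locus names; up to 2 members with the smallest p of each list described by its members; and the Fgfr genes. Genes outside the rule are marked as chosen after their values were seen. The part of the array with bright negative controls was set from control spots alone, as the rectangle around the blocks of an 8 by 8 grid in which at least a share of 0.2 of them exceeded 50 red intensity units above local background on some array, after noticing that small p-values clustered on the array. Tests were checked first on simulated arrays with the real probes' means and spreads. In that simulation of the FGFR1 KO against WT comparison over 39139 probes, limma recovered 18 of 67 probes changed 2-fold, 57 of 67 changed 4-fold and 62 of 66 changed 8-fold, with 11 false calls. A fibroblast list of 30 genes shifted by -1 on the log2 scale among 16579 genes was called by camera (adjusted p = 1.30e-22), with an estimated correlation (adjusted p = 0.00113) and by fry (adjusted p = 1.00e-04), with 0 of the 44 other lists called. The simulated noise was drawn independently for each probe, so the genes of a list were uncorrelated. In the real data the estimated correlation was 0.38 for the fibroblast list and 0.91 for oxidative phosphorylation. The simulation therefore does not show how the list tests behave with correlated genes.

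The alternatives were red processed signal alone scaled to its 75th percentile, red signal after normexp and quantile normalization, Agilent's ratio, green as the tumour channel, A-quantile values, the series matrix, no filter, a filter for signal on all 8 arrays, eBayes with trend and robust settings, array weights, the replicate number as a block, a log2 change of at least 1, the mean of all probes of a gene, and leaving out each array. Leaving out the bright part and leaving out WT 1 and WT 2 were added after seeing the data. The bright part was left out after normalization, so its spots still took part in the loess. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The probe positions relative to the floxed part of Fgfr1 were not examined, as no genome sequence was used here.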

Results

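Gene expression was measured in 8 mouse mammary tumours on 2-colour Agilent arrays. Per the labels, 4 tumours came from mice with a floxed Fgfr1 gene on the K19-tva background (FGFR1 KO) and 4 from control K19-tva mice (WT), all on the FVB strain. K19-tva mice are named for the Krt19 promoter and the avian retrovirus receptor tva. Tumour RNA was taken to be in the red channel and a common human reference RNA in the green channel. The label field names only cy3, while the labelling protocol and the lower spread of green within groups give this assignment, and camera called 0 lists with green as the sample. A value is the log2 ratio of tumour to reference. Red signal was well above background at 68.9% to 83.9% of spots on the FGFR1 KO arrays and at 43.9% to 69.2% on the WT arrays. Green, taken as the common reference, was also lower in this share on the WT arrays (69.45% to 81.99% against 89.37% to 91.45%). The share is therefore not a measure of tumour signal alone. A probe could pass the filter of 4 arrays through the FGFR1 KO arrays alone. All 8 arrays were scanned as 1 slide, with the FGFR1 KO arrays in slide row 1 and the WT arrays in slide row 2, so slide row and genotype cannot be told apart. The labels do not say that the tumours came from separate animals, so p-values measure the spread between these 8 samples, and the number of arrays limits the precision.

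The mean correlation across probes was 0.752 over the 6 pairs of FGFR1 KO arrays, 0.558 over the 6 pairs of WT arrays and 0.598 over the 16 pairs between genotypes, with probes not being independent replicates. WT 2 stood apart, with a mean correlation of 0.379 to the other arrays. On principal component 1, which held 42.7% of the variance, WT 2 scored 152 and WT 1 scored 13.2, while the other 6 arrays scored from -36.3 to -19.6.

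Fgfr1, the targeted gene, encodes fibroblast growth factor receptor 1, and its transcript level was compared first as a check of the labels. The probe that represented the gene, A_55_P1967015 (accession NM_010206), read 0.31 ± 0.11 (SD, n = 4) in FGFR1 KO and 0.31 ± 0.06 (SD, n = 4) in WT tumours. Its difference was 0.00 on the log2 scale, with a 95% confidence interval from -0.28 to 0.28, and the exact permutation p was 1.0 (two-sided, n = 4 per group). The values for FGFR1 KO 1 to 4 were 0.45, 0.27, 0.32 and 0.19, and those for WT 1 to 4 were 0.28, 0.23, 0.38 and 0.33. The mean red signal of this probe, on the log2 scale after A-quantile normalization, was 16.29 in FGFR1 KO and 16.25 in WT. The probe that represented Fgfr4 read 11.03 and 12.57 on that scale. A second probe, A_55_P1967022, differed by -0.10 ± 0.41 (SE), and another, A_55_P2057777, whose spot lay in the bright part of the WT arrays, by -0.49 ± 0.66 (SE), with FGFR1 KO 4 at -1.99 and FGFR1 KO 3 at 1.76. The second probe also read lower on FGFR1 KO 4 than on FGFR1 KO 3 (-0.42 against 1.64), while A_55_P1967015 read 0.19 and 0.32 there. The 3 probes therefore differ in how they vary between arrays. The narrow interval holds for A_55_P1967015 alone and does not show that the transcript level was unchanged. No Fgfr1 probe passed the limma test over all probes (adjusted p = 1.0, 0.951 and 0.841). The position of these probes relative to the floxed part of the gene is not given in the sources used here, so the probes cannot be placed and this comparison does not check the genotype labels.

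**Figure D1:**
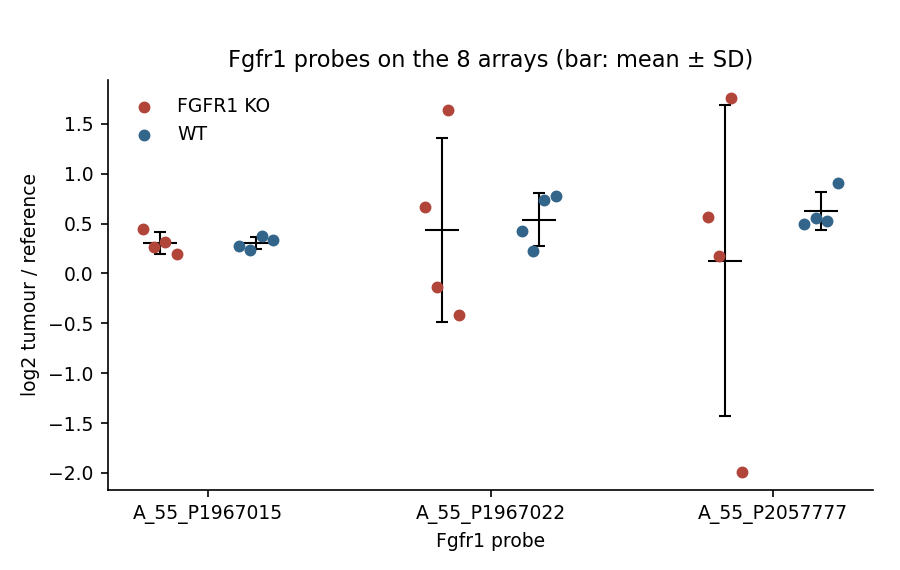
Each point is 1 array, with the log2 ratio of tumour to reference on the vertical axis for the 3 Fgfr1 probes, FGFR1 KO in red and WT in blue, and bars show the mean and SD of 4 arrays. Both groups average 0.31 at probe A_55_P1967015, and at A_55_P2057777 the FGFR1 KO arrays run from -1.99 to 1.76.

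The genotype comparison asked which genes and gene groups differed between FGFR1 KO and WT tumours, with changes given as FGFR1 KO minus WT. Fibroblast and extracellular matrix genes were lower in FGFR1 KO tumours, with all 30 measured members at or below 0, Mfap4 within 0.01 of it, and a median log2 change of -1.16. The list was called by limma's camera test (adjusted p = 3.14e-16 over the 45 lists), but not with a correlation between genes estimated per list (adjusted p = 0.729 with an estimated correlation). Its median on the FGFR1 KO arrays was -1.15, -1.09, -0.68 and -2.04, below the -0.13, -0.51, 0.20 and -0.17 of the WT arrays, with an exact permutation p of 0.0286 (two-sided, n = 4 per group), the smallest that 4 against 4 arrays allow. Of the 45 lists, 3 reached this value, the others being mast cells and eosinophils and angiogenesis regulators, and 0 passed after adjustment over the lists (adjusted exact p = 0.429). Of the 30 members, 0 passed over all probes tested and 14 were lower when adjusted over the list alone. The count of 14 depended on the setting, at 5 with Agilent's log ratio, 7 with red processed signal alone, 0 without FGFR1 KO 2 or FGFR1 KO 4, 2 without WT 1, 4 without WT 3, 7 without FGFR1 KO 1 and 21 without WT 2.

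Lum, which encodes the collagen-binding proteoglycan lumican, differed by -2.195 ± 0.44 (SE) and averaged 1.11 ± 0.88 (SD, n = 4) in FGFR1 KO against 3.30 ± 0.56 (SD, n = 4) in WT tumours. Dpt, which encodes the matrix protein dermatopontin, differed by -2.24 ± 0.48 (SE), with a probe well above background on 1 of 4 FGFR1 KO arrays and a change from -4.19 to -1.39 over settings other than green as the sample. Among further members chosen after their values were seen, the main fibrillar collagen genes Col1a1 and Col3a1 differed by -1.93 ± 0.74 and -1.68 ± 0.60 (SE). The proteoglycan gene Dcn differed by -2.22 ± 0.78, the fibroblast activation marker Fap by -1.55 ± 0.38 and the growth factor receptor gene Pdgfrb by -0.67 ± 0.23 (SE). Each of Lum, Dpt, Fap and Pdgfrb was lower on all 4 FGFR1 KO arrays than on any WT array, while Col1a1, Col3a1 and Dcn overlapped between the groups.

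Genes of the mesenchymal transition were lower as well, with 20 of 24 measured members below 0 and a median of -0.67 (limma's camera, adjusted p = 3.17e-06). The list of matrix proteases and their inhibitors had 23 of 28 members below 0 and a median of -0.48 (camera, adjusted p = 6.53e-05). Each of these 2 lists had adjusted p = 0.729 with an estimated correlation. Their array medians gave an exact permutation p of 0.0571 and 0.257 (two-sided, n = 4 per group). Fn1, which encodes fibronectin, differed by -1.45 ± 0.42 (SE), and Itga5, which encodes a subunit of the fibronectin receptor, by -0.90 ± 0.23 (SE). Of the mesenchymal genes, 0 passed over all probes or adjusted over the list alone. Ctsk, which encodes the collagen-degrading protease cathepsin K, differed by -1.84 ± 0.33 (SE) and was the 1 protease list member that was lower when adjusted over the list alone, against 0 over all probes. That count was 0 with Agilent's log ratio, with trend and robust eBayes and with the bright part left out, and 7 without WT 2. Adamts1, a secreted metalloprotease gene, differed by -1.58 ± 0.42 (SE).

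Part of each WT array was bright at negative-control spots, and 13 of the 30 fibroblast and matrix genes, among them Dpt, lay in it, as did the probes of Itga5, Ctsk and Adamts1. With that part left out, 19 of 19 fibroblast and matrix genes were below 0, 2 of them represented by another probe outside it, with a median of -1.16 (camera, adjusted p = 9.93e-17). The medians without it were -0.60 for mesenchymal transition genes (camera, adjusted p = 2.87e-05) and -0.27 for matrix proteases (camera, adjusted p = 0.0153).

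**Figure D2:**
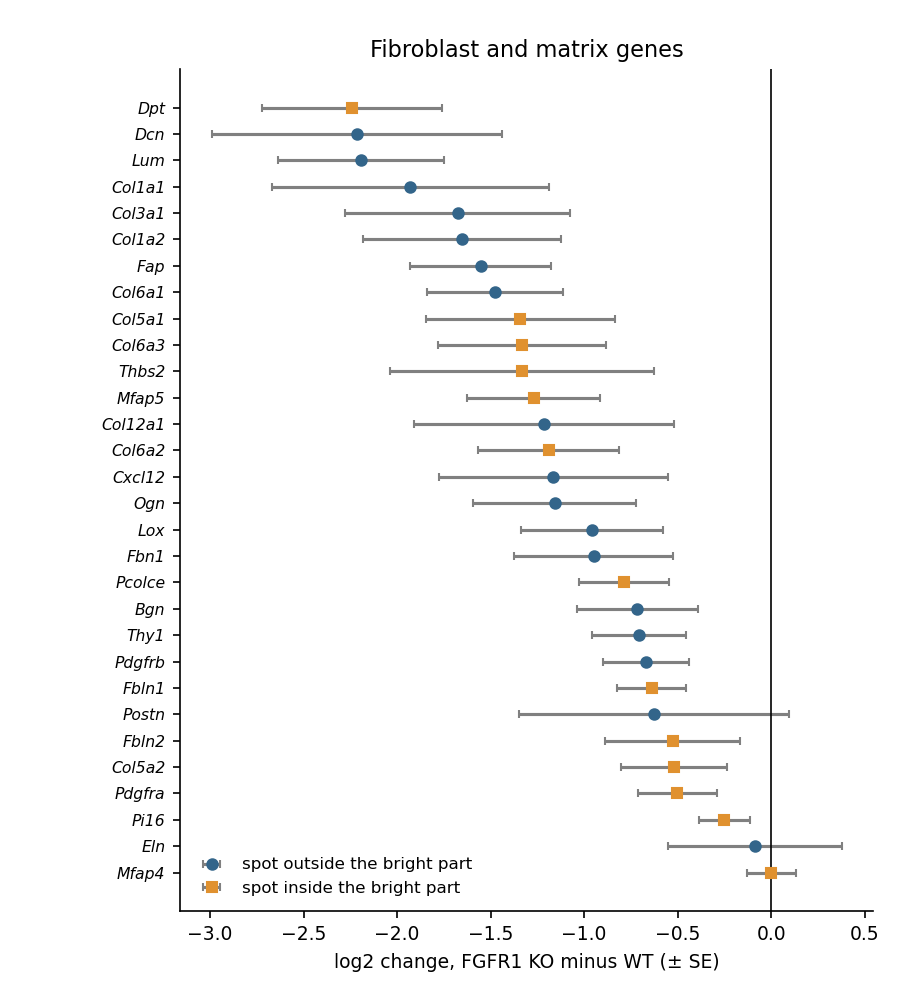
Log2 change (FGFR1 KO minus WT, horizontal axis) of the 30 fibroblast and extracellular matrix genes, with bars for the SE; blue circles are genes whose spot lies outside the bright part of the WT arrays and orange squares those inside it. The changes run from -2.24 for Dpt, whose probe was well above background on 1 of 4 FGFR1 KO arrays, to about 0 for Mfap4.

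Fat, muscle and mitochondrial genes were lower in FGFR1 KO tumours, with fat genes highest on WT 1 and WT 2 and muscle and mitochondrial genes far higher on WT 2 than on any other array. Adipocyte genes had 23 of 24 measured members below 0 and a median of -1.66 (limma's camera, adjusted p = 9.60e-07). Skeletal muscle genes had 22 of 23 below 0 and a median of -2.16 (camera, adjusted p = 3.14e-05), and oxidative phosphorylation genes 34 of 35 below 0 and a median of -0.81 (camera, adjusted p = 3.75e-05). Each of these 3 lists had adjusted p = 0.729 with an estimated correlation, and 0 of their members passed over all probes or adjusted over the list alone. Their array medians gave an exact permutation p of 0.114, 0.286 and 0.457 (two-sided, n = 4 per group). The adipocyte median was 3.32 on WT 1 and 4.33 on WT 2 and at most 0.68 on the other 6 arrays. The muscle median was 8.07 on WT 2, 1.16 on WT 1 and between -0.15 and 0.30 elsewhere, and the oxidative phosphorylation median was 3.00 on WT 2. Pparg, the main transcription factor of fat cell differentiation, differed by -1.36 ± 0.50 (SE), and Plin4, a lipid droplet gene, by -1.61 ± 0.61 (SE), and by -0.86 and -0.96 without WT 2. Cox8b, a cytochrome c oxidase subunit gene of muscle, differed by -3.94 ± 1.55 (SE), and Myl1, a fast muscle myosin light chain gene, by -3.12, with 7.78 on WT 2. Without WT 2, they differed by -2.39 and -1.51. Of the respiratory chain genes, Sdhb differed by -1.37 ± 0.84 and Uqcrc1 by -1.11 ± 0.73 (SE), and by 0.01 and 0.02 without WT 1 and WT 2. Without WT 1 and WT 2, the adipocyte median was -0.09 (camera, adjusted p = 0.791), the muscle median was 0.25 (camera, adjusted p = 0.405). Oxidative phosphorylation then turned to 0.14, with 0 of 35 members below 0 (camera, adjusted p = 0.0312). Without WT 2 alone, the oxidative phosphorylation median was -0.08 (camera, adjusted p = 0.548), a call also lost with array weights (median -0.35, adjusted p = 0.108), and the muscle median was -0.32 (camera, adjusted p = 0.0262).

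Endothelial cells were represented by a list with 20 of 25 measured members below 0 and a median of -0.37 (limma's camera, adjusted p = 0.0157, and adjusted p = 0.729 with an estimated correlation). Pecam1, which encodes the endothelial adhesion molecule CD31, differed by -0.64 ± 0.16 (SE), and Lyve1, a lymphatic vessel marker, by -0.85 ± 0.32 (SE; -0.57 without WT 1), and 0 members passed over all probes or adjusted over the list alone. The endothelial call was lost without WT 1 (median -0.20, adjusted p = 0.252), without WT 2 (median -0.22, adjusted p = 0.101), without FGFR1 KO 2 (median -0.30, adjusted p = 0.143), and without both WT 1 and WT 2 (median 0.05, adjusted p = 0.666). It was also lost with array weights (median -0.23, adjusted p = 0.133) and over probes above background on all 8 arrays (median -0.27, adjusted p = 0.0938).

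**Figure D3:**
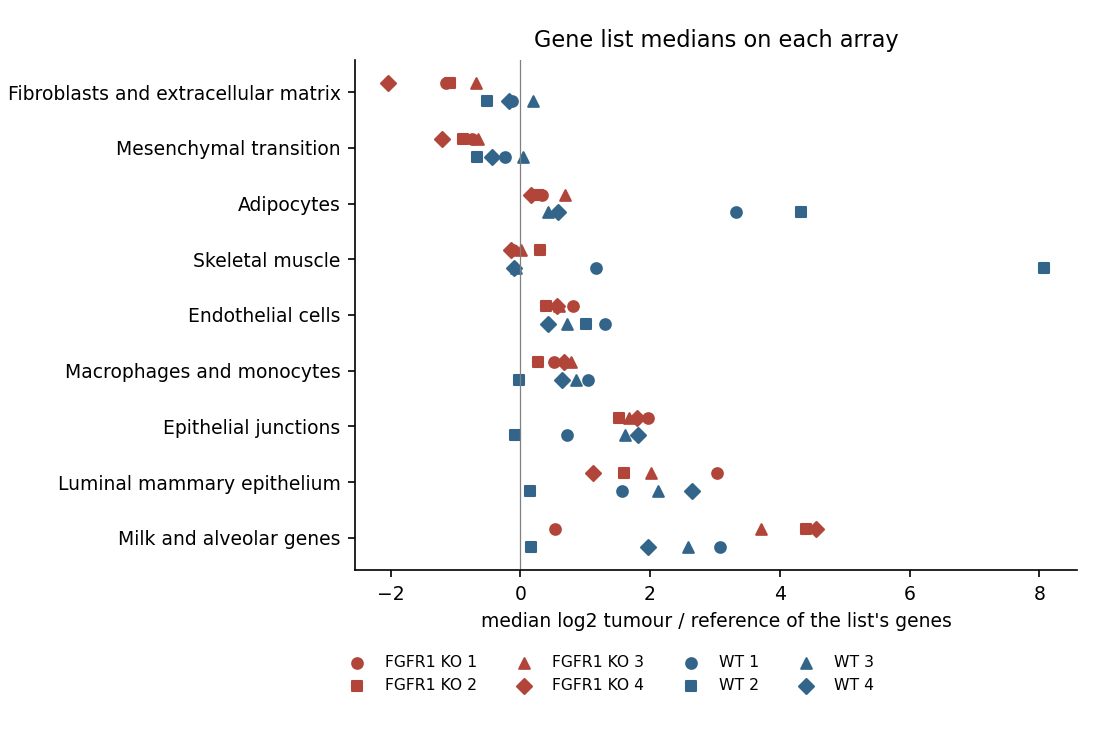
Median log2 ratio of tumour to reference (horizontal axis) over the tested genes of 9 gene lists on each of the 8 arrays, with FGFR1 KO in red, WT in blue and a symbol for each replicate number. The fibroblast medians of the 4 FGFR1 KO arrays all lie below those of the WT arrays, while the muscle median of WT 2 is 8.07 and the milk median of FGFR1 KO 1 is 0.54.

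Junction, milk and luminal genes were higher in FGFR1 KO tumours, with WT 2 the lowest array in the median of these 3 lists and WT 1 low in that of junction genes. The other epithelial lists were not called, with a median of 0.19 for basal and myoepithelial cells (camera, adjusted p = 0.399) and 0.09 for squamous differentiation (adjusted p = 0.511). Without WT 1 and WT 2, the basal median turned to -0.24 (adjusted p = 0.0275). Epithelial junction genes had 25 of 27 measured members above 0 and a median of 0.72 (limma's camera, adjusted p = 1.18e-07). Milk and alveolar genes had 21 of 22 above 0 and a median of 1.18 (camera, adjusted p = 3.29e-05), and luminal mammary genes 18 of 24 above 0 and a median of 0.60 (camera, adjusted p = 0.0468). Each of these 3 lists had adjusted p = 0.729 with an estimated correlation, and 0 members of any of them passed over all probes or adjusted over the list alone. Their array medians gave an exact permutation p of 0.2, 0.286 and 0.714 (two-sided, n = 4 per group). Marveld2, which encodes the junction protein tricellulin, differed by 1.48 ± 0.49 (SE), and Tjp3, a tight junction scaffold gene whose probe lay in the bright part, by 0.85 ± 0.29 (SE). Wap, which encodes whey acidic protein, differed by 4.70 ± 1.39 (SE) over 3 FGFR1 KO and 4 WT values, with no value on FGFR1 KO 1, the FGFR1 KO array lowest in milk genes. Olah, a thioesterase gene of milk fatty acid synthesis, differed by 2.23 ± 0.78 (SE) and read 0.37 on FGFR1 KO 1 against 3.25 to 4.30 on the other FGFR1 KO arrays. Prlr, which encodes the prolactin receptor, differed by 2.695 ± 1.22 (SE), and Gata3, a transcription factor of the luminal lineage, by 1.73 ± 0.83 (SE), and by 1.69 and 0.92 without WT 2. Among genes chosen after their values were seen, the luminal keratin gene Krt8 differed by 1.56 ± 1.38 (SE) and the E-cadherin gene Cdh1 by 0.57 ± 0.40 (SE), and by -0.03 and 0.18 without WT 2. Krt8 read -3.94 on WT 2 and between 1.41 and 3.27 on the other 7 arrays. Without WT 1 and WT 2, Krt8 and Cdh1 turned to -0.42 and -0.08. The milk median was 0.54 on FGFR1 KO 1 and 0.17 on WT 2, against 3.71 to 4.56 on the other FGFR1 KO arrays and 1.97 to 3.08 on the other WT arrays. Without WT 1 and WT 2, the junction median was 0.11 (camera, adjusted p = 0.144), the milk median 0.28 (camera, adjusted p = 0.101) and the luminal median -0.18 (camera, adjusted p = 0.446). The luminal call was also lost without the bright part (median 0.46, adjusted p = 0.21), without FGFR1 KO 1 (median 0.59, adjusted p = 0.583), FGFR1 KO 3 (0.49, 0.0522), WT 1 (0.53, 0.135) or WT 2 (0.11, 0.492), and held in 7 of 22 settings.

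Genes of FGF signalling showed no called shift as lists. Of 17 FGF ligand genes, 13 were below 0, with a median of -0.14 (limma's camera, adjusted p = 0.457), and of 23 feedback genes of FGF and ERK signalling, 14 were above 0, with a median of 0.15 (camera, adjusted p = 0.278). Fgf7, a stromal growth factor gene, differed by -0.75 ± 0.35 (SE; -0.48 without WT 2) and Fgf1 by 0.37 ± 0.19 (SE). The probe of Fgf7 lay in the bright part and that of Fgf1 outside it. The FGF receptors and coreceptors had 7 of 9 measured members below 0 and a median of -0.12 (camera, adjusted p = 0.312). Fgfr4 differed by -1.98 ± 0.53 (SE), lower on all 4 FGFR1 KO arrays than on any WT array (exact permutation p = 0.0286, two-sided, n = 4 per group). It was the 1 receptor lower when adjusted over the list alone, against 0 over all probes (limma, adjusted p = 0.40). No receptor was lower over the list alone without FGFR1 KO 1, FGFR1 KO 2, FGFR1 KO 4 or WT 1, with Agilent's log ratio, with red signals alone or in 6 other settings. A second Fgfr4 probe, A_55_P2120055, differed by 0.11 ± 0.16 (SE), so the 2 probes of this gene disagreed. Fgfr2, whose probe lay in the bright part, differed by 0.43 ± 0.28 (SE; 0.17 without FGFR1 KO 1). Fgfr3 differed by 0.22 ± 0.18 (SE; 0.11 to 0.34 with 1 array left out, -0.04 with red processed signal alone) and Fgfrl1 by -0.55 ± 0.31 (SE; -0.28 without FGFR1 KO 4), and none of these passed. In the feedback list, Spry4, which encodes an inhibitor of receptor tyrosine kinase signalling, was higher by 0.79 ± 0.16 (SE) and the cytokine gene Lif, whose probe lay in the bright part, lower by -0.89 ± 0.18 (SE) when adjusted over the list alone, against 0 over all probes (limma, adjusted p = 0.226 and 0.224).

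Immediate early genes had 17 of 22 measured members below 0 and a median of -0.49 (limma's camera, adjusted p = 0.00402, and adjusted p = 0.729 with an estimated correlation). Klf4, a growth-responsive transcription factor gene, differed by -1.08 ± 0.30 (SE), and Ccn1, which encodes a secreted matricellular protein, by -1.02 ± 0.29 (SE), and 0 members passed over all probes or adjusted over the list alone. The probe of Klf4 was well above background on 3 FGFR1 KO and 2 WT arrays, and that of Ccn1 lay in the bright part. Without WT 1 and WT 2 the median was -0.11 (camera, adjusted p = 0.111), and the call was also lost over probes above background on all 8 arrays. Mitosis genes had 20 of 29 members above 0 and a median of 0.15 (camera, adjusted p = 0.122), with the mitotic kinesin genes Kif20a at 0.39 ± 0.15 and Cenpe at -0.40 ± 0.19 (SE) and 0 members passing over all probes or adjusted over the list alone. The probe of Cenpe lay in the bright part and that of Kif20a outside it. Mitosis genes were called higher with red signals alone, with Agilent's log ratio and in 4 other settings, with a median of at most 0.38, among them without FGFR1 KO 1 (0.29, adjusted p = 0.0183), FGFR1 KO 3 (0.21, 0.0192) or WT 3 (0.20, 0.0412).

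Macrophage and monocyte genes had 19 of 28 measured members below 0 and a median of -0.17 (limma's camera, adjusted p = 0.189). Mrc1 and Cd163, scavenger receptor genes of tissue macrophages, differed by -1.41 ± 0.43 and -0.72 ± 0.21 (SE), and 0 members passed over all probes or adjusted over the list alone. Macrophage genes were called lower without WT 2 (median -0.49, adjusted p = 5.56e-05) and in 5 other settings, among them Agilent's log ratio and array weights. Mast cell and eosinophil genes had 6 of 13 members below 0, with a median of 0.09, a mean of -0.24 and a camera test pointing lower (adjusted p = 0.429). Their median was 0.12, -0.05, 0.09 and -0.01 on the FGFR1 KO arrays, below the 0.31, 0.30, 0.28 and 0.13 of the WT arrays (exact permutation p = 0.0286, two-sided, n = 4 per group). The list was the 1 of 45 with an adjusted p under 0.05 in fry's mixed test for change in either direction (adjusted p = 0.00367). The list's median was -0.77 inside the bright part and 0.27 outside it, where 3 of 9 members were below 0. When adjusted over the list alone, 3 of the 13 were lower, against 0 over all probes. These were Hdc, the histamine-forming enzyme gene, at -1.42 ± 0.24 (SE), and the mast cell protease genes Mcpt4 at -2.10 ± 0.41 (SE) and Cma1, named after its value was seen, at -1.19 ± 0.30 (SE). The probes of Hdc and Mcpt4 lay in the bright part and that of Cma1 outside it.

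Over single probes, limma called 4 of 39795 lower and 0 higher at an adjusted p under 0.05, and it called 0 of 16761 genes, with a smallest adjusted p of 0.0608. At an unadjusted p under 0.05 there were 3376 probes, 1444 higher and 1932 lower, and 1320 genes, where chance alone gives 1990 probes and 838 genes. The 34 other splits of the arrays into 4 and 4 gave 639 to 3261 probes. The values of the 4 FGFR1 KO arrays lay all above or all below those of the WT arrays for 729 genes, 4.35% against the 2.86% that chance gives. Of the 729, 310 lay above and 419 below. Genotype also divides the arrays with the bright part from those without it, so this excess cannot tell the 2 apart. The 4 called probes carry no gene name and are long intergenic RNA probes on mm9, at chromosome 18 from 36480559 to 36481146, chromosome 5 from 122982442 to 123000053, chromosome 10 from 84005221 to 84022896 and chromosome 1 from 52706748 to 52712402. They differed by -1.45, -1.44, -1.32 and -1.36 on the log2 scale, each with an SE of 0.13 or 0.14 and a limma adjusted p of 0.04, and were well above background on 2 or 3 FGFR1 KO and 2 WT arrays. All 4 lay in the bright part of the WT arrays, and with that part left out limma called 0 of 27056 probes (smallest adjusted p = 0.734, with 1272 higher and 520 lower at an unadjusted p under 0.05). The loess was still fitted with the spots of that part, and the median change over the remaining probes was 0.059. The excess of higher probes there cannot be told apart from a shift by the normalization. The split also moved with the scaling, to 2873 higher and 852 lower with Agilent's log ratio and to 2780 higher and 764 lower with red processed signal alone, settings that moved the median over all probes to 0.116 and 0.144 from 0.016.

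The bright part covered spot rows 97 to 336 and spot columns 83 to 164 of arrays with 384 by 164 spots. Of its 96 negative-control spots, 42, 17, 45 and 22 exceeded 50 red intensity units above local background on WT 1 to 4 and 0 on every FGFR1 KO array, while at most 2 of the 212 outside it did on any array. Of the tested probes, 32.8% lay in it, and 11.1% of these were lower at an unadjusted p under 0.05, against 1.83% outside.

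**Figure D4:**
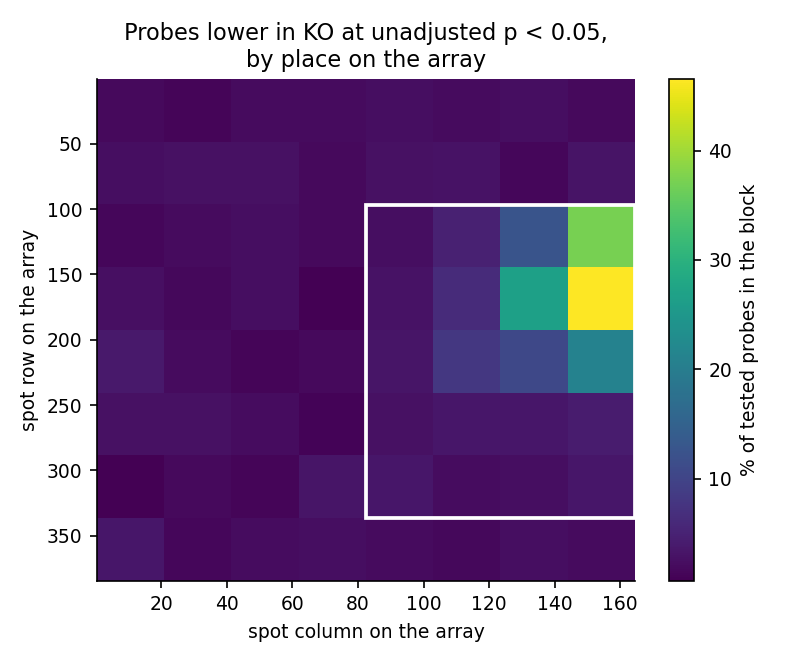
Share of tested probes (colour, in %) that were lower in FGFR1 KO at an unadjusted p under 0.05, in 64 blocks of the array by spot column and spot row; the white frame marks the bright part found from negative-control spots. Inside the frame the share is 11.1% and outside it 1.83%.

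Because 0 genes passed in either direction, the 8 with the smallest p in each direction are given as values. The 8 higher in FGFR1 KO were the phosphoinositide phosphatase gene Inpp5j at 1.29 ± 0.23 (SE), the transporter gene Slc7a4 at 1.17 ± 0.21, the semaphorin gene Sema4g at 1.02 ± 0.20 and the scaffold gene Magi3 at 0.89 ± 0.17. The others were the olfactory receptor gene Olfr120 at 0.88 ± 0.20, Spry4 at 0.79 ± 0.16, Cep126 at 0.66 ± 0.14 and the homeobox gene Pbx2 at 0.63 ± 0.15. Their limma adjusted p ran from 0.166 for Inpp5j to 0.297 for Pbx2, and of their probes that of Sema4g lay in the bright part. Inpp5j and Spry4 were well above background on 1 of 4 WT arrays. Cep126 was not well above background on any WT array, and its red signal was at least 1.08-fold higher in FGFR1 KO. Fewer spots were well above background on the WT arrays in both channels, so these counts of arrays do not by themselves show lower expression there. The 8 lower were Spaca9 at -1.38 ± 0.15 (SE), Olfr706 at -1.44 ± 0.17, Mepe at -1.32 ± 0.16, Tcp11l1 at -1.41 ± 0.17, Olfr715 at -1.33 ± 0.17, Ptchd3 at -1.52 ± 0.21, the histidine ammonia-lyase gene Hal at -1.36 ± 0.19 and Xlr5c at -1.09 ± 0.16. Their limma adjusted p ran from 0.0608 for Spaca9 to 0.0982 for Xlr5c, and all 8 probes lay in the bright part. That of Olfr706 was well above background on 1 of 4 FGFR1 KO arrays. Second probes of Spaca9 and Tcp11l1 differed by 0.01 and 0.04.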

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

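The tests of the bright part, of dim signal, of the fibroblast list and of WT 2 were chosen after the results were seen, while the counts over other splits of the arrays were planned.

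Probes lower in FGFR1 KO clustered in 1 part of the array. Of the 200 smallest p-values, 88% lay in the part where negative-control spots were bright on the WT arrays, which held 32.8% of the tested probes, and all 4 called probes lay there. Dim signal alone is argued against as the cause, since among probes of dim signal outside that part 1.24% were lower at an unadjusted p under 0.05, against 18.5% inside it. Of the 35 splits of the arrays into 4 and 4, 1 called as many as 4 probes, the real one, and the highest other called 0. A first rank among 35 splits is the most this test can give, so chance is not excluded for the probes as a count. The real split also divides the arrays with the bright part from those without it, so the count cannot tell genotype from that part. A candidate explanation for the 4 probes is extra signal in that part of the WT arrays, which were also in the other slide row, and an effect of genotype on these 4 probes stays open but untested.

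Fibroblast and matrix genes were lower on all 4 FGFR1 KO arrays. The bright part is argued against as the whole cause by a median of -1.16 over 19 of 19 negative genes with it left out, and fat and muscle in WT 1 and WT 2 by a median of -1.18 without them. For a lower share of every stromal cell type, the fibroblast median was set against the mean of the endothelial, pericyte and macrophage medians. The FGFR1 KO minus WT change in that difference was -0.990 (exact permutation p = 0.0286, two-sided, n = 4 per group). It read -1.95, -1.42, -1.26 and -2.54 on FGFR1 KO 1 to 4 and -0.9995, -1.03, -0.45 and -0.74 on WT 1 to 4. The fibroblast list was picked for medians that already separated the groups, so this p adds little. Array medians changed by -1.09 for fibroblasts against -0.27, 0.05 and -0.07 for endothelial, pericyte and macrophage genes, so these did not fall equally over all 8 arrays. The 2 smallest changes lean on 1 array each. Pericyte genes read 1.075 on FGFR1 KO 1 against 0.27 to 0.37 on the other FGFR1 KO arrays. Macrophage genes read -0.01 on WT 2 against 0.64 to 1.05 on the other WT arrays, and were called lower by camera without WT 2. Adipocyte genes were not part of the test, so it does not cover every stromal cell type. Of the 30 genes, 6 are in another list. Fewer fibroblasts, or lower matrix expression per fibroblast, may follow from the genotype, but slide row and genotype cannot be told apart on this slide, so both stay open.

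WT 2 stood apart from the other arrays. On WT 2, 60.4% of red spots were well above background, more than the 43.9% of the lowest array, WT 1. The red median signal of WT 2 was 160, the lowest of the WT arrays, against 256 on WT 1. FGFR1 KO 2 was lower still at 116.5, with a mean correlation of 0.658 to the other arrays. The 2 measures of signal differ, so the share above background does not settle whether WT 2 was a weak array. Skeletal muscle genes were highest on WT 2 for 22 of 23 and adipocyte genes for 19 of 23 members compared, and the abundant muscle genes Acta1 and Ckm, chosen after their values were seen, read 9.61 and 8.97 on WT 2. A candidate explanation is muscle and fat in the tissue piece of WT 2, and what brought them there was not tested. None of the 23 muscle genes is in another list, and 10 were above background on all other 7 arrays.

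Over gene lists, 10 of the 35 splits called as many as the real 18, with a highest other of 24 for FGFR1 KO 1, WT 1, WT 3 and WT 4 against the rest, so chance is not excluded for the count of lists. The 35 splits called from 9 to 24 lists each, and camera with an estimated correlation called 0 for the real one. For genes, the real count was 0 and the highest other 0, so 35 of 35 splits reach it by construction and the count says nothing about chance.

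Of 241 groups of 4 arrays, 20 held an array whose gap to the nearest other took an unusually large share of the group's range, where chance gives 5%, or 12.1. On the skeletal muscle list, WT 2 stood at 8.07 against -0.10 to 1.16 on the other WT arrays (share 0.8462), and on the heat shock list at 0.32 against -0.33 to -0.28 (0.9268). WT 1 stood at 1.28 against -0.36 to -0.17 for B and plasma cell genes (0.8832) and at -0.22 against -0.07 to -0.04 for angiogenesis regulators (0.8441). FGFR1 KO 1 stood at 1.07 against 0.27 to 0.37 for pericyte and smooth muscle genes (0.8765), and FGFR1 KO 2 at -0.17 against -0.01 to 0.02 for T and NK cell genes (0.8592). FGFR1 KO 4 stood at 0.22 against 0.30 to 0.31 for other receptor tyrosine kinases (0.8904) and at -0.36 against -0.13 to -0.09 for glucose, insulin and PI3K signalling (0.865).

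Of single probes and genes, WT 4 read 0.91 against 0.49 to 0.56 at Fgfr1 probe A_55_P2057777 (share 0.8376), and FGFR1 KO 1 read 0.04 against -0.26 to -0.25 at Fgfr4 probe A_55_P2120055 (0.9649). WT 1 was the array apart for Cma1, at 1.82 against 0.65 to 0.84 (0.841), and for Mrc1, at 4.31 against 2.42 to 2.59 (0.9091). FGFR1 KO 3 was apart for Cox8b, at 0.96 against -0.38 to -0.29 (0.9313), for Fap, at 1.76 against 0.79 to 0.94 (0.844), and for Inpp5j, at 2.07 against 1.18 to 1.27 (0.9). FGFR1 KO 4 was apart for Gata3, at 1.05 against 2.91 to 3.17 (0.8772), and FGFR1 KO 2 for Marveld2, at 3.26 against 2.77 to 2.82 (0.8921). Lif had an array apart in both groups, FGFR1 KO 2 at 0.07 against -0.25 to -0.21 (0.8565) and WT 3 at 0.27 against 0.88 to 0.90 (0.976). The scanner software marked 772 spots as outliers on FGFR1 KO 1 against 290 to 304 on the other FGFR1 KO arrays (0.971).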

How the results depend on the processing

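Leaving out the bright part of the array and leaving out WT arrays 1 and 2 were chosen after seeing the data, and the other alternatives were planned. The 4 called probes became 0 with red processed signal, red normexp and quantile, Agilent's log ratio, green as the sample, signal on all 8 arrays, trend and robust eBayes, the replicate block, the bright part left out (0 of 27056) and without WT arrays 1 and 2. They became 27 with A-quantile values, 139 with no filter and 11 with array weights, of which 27, 138 and 11 lay in the bright part, and 0 to 1 with any 1 array left out (1 without WT 4). The 0 called genes became 8 with A-quantile values, 2 with the series matrix, 40 with no filter, 4 with array weights and 0 to 1 with 1 array left out (1 without WT 4). The 18 called lists became 0 with green as the sample, with an estimated correlation and with fry's test of a shift in 1 direction (4 lists at an unadjusted p under 0.05), and 11 (without WT 1) to 20 with 1 array left out. If green is the common reference, as taken here, a loss of calls with green was fixed in advance and does not test them. Oxidative phosphorylation reversed without WT arrays 1 and 2, to a median of 0.14; leaving out the 2 arrays with its highest medians is that setting's construction. For the rest, the cause was not tested.

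The Fgfr1 change at probe A_55_P1967015 ranged from -0.05 to 0.12. The mean correlation within less between genotypes was 0.0568 and ranged from 0.0002 to 0.122. Of 64 named genes other than Fgfr1, 0 passed in the main fit. Over these, 1268 of 1286 alternative values did not pass either and 18 did, and 43 differed in sign, 32 of them with green. Values that stayed short of the threshold do not show that a change is stable. Over 45 lists, 903 of 1080 kept their side of the threshold, 55 newly passed, 121 no longer passed and 1 reversed. Of the 1080, 92 differed in direction, 26 of them with green. Deviations of arrays with the same number correlated at -0.0389, 0.0115, 0.109 and -0.106, which gave no sign that the numbers pair the samples. Each number is also the slide column of its array, and a pairing by handling is not excluded. The share of red spots well above background reached its lowest value, 43.9%, on WT 1. Red median signals were not lower on the WT arrays as a group, at 160 to 256 against 116.5 to 279 on the FGFR1 KO arrays.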

Other observations

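The leave-one-array settings named here were planned, while leaving out the bright part or both WT 1 and WT 2 was chosen after the results were seen. Of the 28 lists outside the report, limma's camera called 6 lower and 1 higher in FGFR1 KO. Called lower were hypoxia and glycolysis genes (25 of 31 measured members below 0, median -0.34, adjusted p = 0.00189), MHC class I presentation (12 of 16, -0.49, 0.00779), B and plasma cells (14 of 17, -0.54, 0.0101), the interferon response (23 of 29, -0.22, 0.0157), T and NK cells (21 of 30, -0.11, 0.0338) and fatty acid and cholesterol synthesis (20 of 28, -0.32, 0.0403). Called higher were ribosomal proteins (38 of 45 above 0, 0.14, 0.0279). Each of these 7 lists had adjusted p = 0.729 with an estimated correlation, and 0 of their members passed over all probes or adjusted over the list alone.

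Hypoxia and glycolysis genes were no longer called without FGFR1 KO 1 (adjusted p = 0.0807). The MHC class I presentation call was lost without FGFR1 KO 4 (0.0506) or WT 1 (0.262), and the B and plasma cells call without WT 1 (median -0.05, adjusted p = 0.554). The interferon response call was lost without FGFR1 KO 1 (0.0889), FGFR1 KO 4 (0.393), WT 1 (0.479), WT 3 (0.0563) or WT 4 (0.0507). The T and NK cells call was lost without FGFR1 KO 2 (0.171) or WT 1 (0.698). The fatty acid and cholesterol synthesis call was lost without FGFR1 KO 1 (0.379), WT 1 (0.315) or WT 4 (0.112), and the ribosomal proteins call without FGFR1 KO 2 (0.387), FGFR1 KO 4 (0.597) or WT 2 (0.675). Ribosomal proteins were not called with the bright part left out either (median 0.14, adjusted p = 0.181).

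Without both WT 1 and WT 2, the calls were lost for B and plasma cells (median -0.18, adjusted p = 0.0691), T and NK cells (-0.01, 0.376), fatty acid and cholesterol synthesis (-0.03, 0.44) and ribosomal proteins (-0.02, 0.676). They held for Hypoxia and glycolysis genes (-0.30, 0.000269), the interferon response (-0.39, 0.00388) and MHC class I presentation (-0.31, 0.0312). In the same setting, lists not called over all 8 arrays were called lower. These were basal and myoepithelial cells, from a median of 0.19 to -0.24 (adjusted p = 0.0275), chemokines and inflammatory cytokines (-0.32, 0.00383), angiogenesis regulators (-0.07, 0.0358) and Wnt pathway targets (-0.14, 0.0275), besides macrophages. Of 22 settings, the T and NK cells call was lost in 9 and the fatty acid and ribosomal calls in 11 each. The B and plasma cells call was also lost over probes above background on all 8 arrays. All 7 calls were also lost with green as the sample. Green was taken as the common reference, so if that assignment is right, this loss was fixed in advance and does not test the calls.

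Lists not called by camera were chemokines and inflammatory cytokines (median -0.04, adjusted p = 0.0541), heat shock (-0.22, 0.0541), angiogenesis regulators (-0.31, 0.0758, with array medians of -0.24, -0.40, -0.30 and -0.56 in FGFR1 KO, all below the -0.22, -0.04, -0.06 and -0.07 of WT, and a median of -0.48 inside the bright part and 0.03 outside it), erythroid genes (-1.08, 0.082), dendritic cells and MHC class II (-0.30, 0.0858), TGF-beta and BMP (-0.12, 0.189), DNA replication and G1/S (0.09, 0.249), neutrophils (-0.01, 0.281), basement membrane (-0.16, 0.374), Notch (-0.07, 0.377), basal and myoepithelial cells (0.19, 0.399) and glucose, insulin and PI3K signalling (-0.07, 0.457). Squamous differentiation (0.09, 0.511), EGF family and other RTK ligands (-0.01, 0.526), nerve and Schwann cells (0.05, 0.555), Wnt targets (-0.11, 0.723), other receptor tyrosine kinases (0.02, 0.952) and interstitial lymphatic and lymph node stroma (0.06, 0.952) were not called either. Nor were 3 lists whose median, mean and test differed in sign: apoptosis and p53 targets (median -0.06, mean 0.10, higher, adjusted p = 0.429), pericytes and smooth muscle (median 0.09, mean -0.15, lower, 0.952) and the unfolded protein and integrated stress response (median 0.12, mean -0.03, higher, 0.952). Adjusted over the list alone, Ndufa4l2 (chosen after its value was seen) was lower among pericyte genes at -0.74 ± 0.17 (SE), Hdc among neutrophil genes and Lif among chemokine genes, against 0 over all probes, and the spots of all 3 lay in the bright part.

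Leaving out 1 array also called lists that were not called over all 8, and angiogenesis regulators, chemokines, dendritic cells, erythroid genes and heat shock were also called lower in some settings of scaling, filter or fit. Without FGFR1 KO 1 these were, besides mitosis, DNA replication and G1/S (median 0.22), basement membrane (-0.38), dendritic cells and MHC class II (-0.33), chemokines and inflammatory cytokines (-0.12) and angiogenesis regulators (-0.38). Dendritic cells and MHC class II were also called without WT 2 (-0.58) or WT 4 (-0.32), chemokines and inflammatory cytokines without WT 2 (-0.30), angiogenesis regulators without WT 2 (-0.09), heat shock without FGFR1 KO 2 (-0.37) or WT 3 (-0.25), and erythroid genes without FGFR1 KO 3 (-1.22).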
